A study of Mus musculus with 6 samples.

How the data were processed

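The study profiled 1 whole tumour from each of 6 MMTV-PyMT mice, 3 dosed with vehicle (DMSO) and 3 with the class IIa histone deacetylase inhibitor TMP195, on Affymetrix arrays. Total RNA was extracted on spin columns with DNase treatment and labelled with biotin, per the labels' protocols. The values were summarised by RMA with Affymetrix Power Tools, per the submitters' processing notes. RMA as usually run corrects background, quantile normalizes the arrays to each other and summarises probes into a probe set. Tool versions and any filter on probe sets are not given in the sources used here. The deposited values are array signal intensity, with 1 column per tumour and 27359 probe sets. Their scale is not stated. They were taken as linear, since every value was above 0, the column medians (45.6, 44.8 and 46.4 for vehicle tumours 1 to 3; 46.0, 45.1 and 45.2 for TMP195 tumours 1 to 3) and the highest values, from 8137 to 8873, lay far above a log2 range, whereas RMA itself gives log2 values. Whether the values were centred by probe set is not stated either, and their range shows no centring. No scanner files were used here, so background and normalization could not be varied from the raw signal. Quantile normalization gives the arrays nearly the same distribution, so a shift of most genes in one direction would not be visible.

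Each tumour was placed in its dosing group by its label. Probe sets were named through the platform's annotation table, with symbols looked up by Entrez ID in a RefSeq gene table of assembly GRCm38.p6. 21784 probe sets had 1 gene symbol, 1620 had several and 3955 had none. The Entrez IDs of 21693 probe sets were found, and 0 symbols changed. Probe sets with several symbols were not named. Where a gene had more than 1 probe set, as 995 genes did, the one with the highest mean over all tumours stood for it, which left 19937 genes. A second probe set of Hdac4 differed by 0.04 ± 0.10 (SE) and one of Mef2d by 0.28 ± 0.14 (SE), in the same direction as the ones used. The remaining 7422 probe sets were tested as well, with 0 past an adjusted p of 0.05 in limma and 203 at an unadjusted p under 0.05. No probe set was left out for low intensity.

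Log2 intensities were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior), two-sided, with TMP195 minus vehicle as the contrast, no covariate and Benjamini-Hochberg adjustment over all genes. The prior had 2.93 degrees of freedom beside 4 residual ones. Differences are log2 TMP195 minus vehicle, and intervals are 95% moderated intervals. Of 40 gene lists, 19 of cell type markers and 21 of processes, 39 had at least 5 measured genes and were tested with limma's camera at a preset correlation of 0.01 between genes. The lists held 552 genes, of which 512 were measured. Marker lists describe transcript levels in a whole tumour, not numbers of cells. Camera with an estimated correlation, fry and exact permutation of list means were run beside it. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the table and drew the plots.

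The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took up to 10 genes per direction past an adjusted p of 0.05 and filled up with genes of the smallest unadjusted p whose difference was at least 1.5-fold and whose groups did not overlap. Beside 44 genes eligible in this way, it passed over 8 predicted, olfactory or vomeronasal genes. It also took up to 4 members of each described list by unadjusted p, the class IIa deacetylases, and Adgre1, Csf1r and Cd68. Genes named for single tumours in the closing section were chosen after their values were seen.

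The alternatives were the replicate number as a block, a trended robust prior, median centring, cyclic loess, leaving out genes below the 30th percentile of mean intensity, testing every probe set, array weights, other thresholds and leaving out each tumour in turn. Leaving out both vehicle tumour 2 and TMP195 tumour 2 was added after seeing the data. The pipeline was tested on simulated data with the spread of these arrays. In 5 simulations of 19937 genes with 200 changed genes each, limma called 72.4% of genes changed 2-fold and 0.0324% of unchanged genes. The changed genes were altered 1.5, 2, 4 or 8-fold in equal numbers and were adjusted together. Camera called 15 of 15 lists shifted by 0.5 on the log2 scale and 0 of 180 others. In these simulations genes varied independently of each other.

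For the closing section, each tumour was compared gene by gene with the median of the other 5 tumours, in the same way for all 6. The genes above the 30th percentile of intensity that had a position in the RefSeq table, 13947 in all, were put in chromosome order, and the median difference was taken over every window of 9 neighbouring genes. The highest and lowest windows were set against 1000 shuffled gene orders. The positions served only to order genes, since no genome build is given for the array values. In 5 simulations, 30 neighbouring genes were raised by 1 on the log2 scale in shuffled values of TMP195 tumour 1. Of the windows centred on them 150 of 150 passed 0.5, and 0 others did. Shuffled orders alone gave at most 0 windows above 0.5 in that tumour and at most 14 in TMP195 tumour 2. The simulations therefore do not give the number of false windows in TMP195 tumour 2. The spread of each list's mean within the groups was set against 10000 random lists matched on intensity.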

Results

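Gene expression was measured in whole mammary tumours from 6 female FVBN mice that carry the MMTV-PyMT transgene. In this model a mammary tumour virus promoter drives the polyoma virus middle T antigen in the mammary epithelium, and the mice develop mammary tumours. The mice were 75 to 90 days old when tumour burden was assessed. They received either the vehicle, DMSO, or TMP195 at 50 mg/kg by daily injection into the abdomen, with 3 mice in each group. TMP195 inhibits the class IIa histone deacetylases, a family made up of Hdac4, Hdac5, Hdac7 and Hdac9. The sources used here disagree on how long the mice were dosed: one description gives 5 days and another gives 2 weeks. A single tumour was taken from each mouse, so the 3 tumours of a group are separate animals. RNA from each tumour was hybridised to an Affymetrix array. Median intensity over all probe sets was 45.6, 44.8 and 46.4 in vehicle tumours 1, 2 and 3, and 46.0, 45.1 and 45.2 in TMP195 tumours 1, 2 and 3. The number of arrays limits the precision of every difference given here. The median half-width of the 95% confidence interval of a gene's difference was 0.30 on the log2 scale, or 1.23-fold.

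The tumours did not separate by dosing in their expression as a whole. Spearman correlations across the 19937 genes, which are not independent replicates, lay between 0.982 and 0.997 for pairs of tumours, and the highest was between vehicle tumour 3 and TMP195 tumour 1. The first principal component held 43.5% of the variance and set TMP195 tumour 2, with a score of -44.6, apart from the other 5 tumours, whose scores ran from -2.11 to 15.5. The second component held 24.1% and set vehicle tumour 2 apart, with a score of 30.7. In TMP195 tumour 2, 150 genes lay more than 2-fold above every other tumour and 89 lay more than 2-fold below. In vehicle tumour 2 these counts were 60 and 5, and in the remaining 4 tumours no count exceeded 12.

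**Figure D1:**
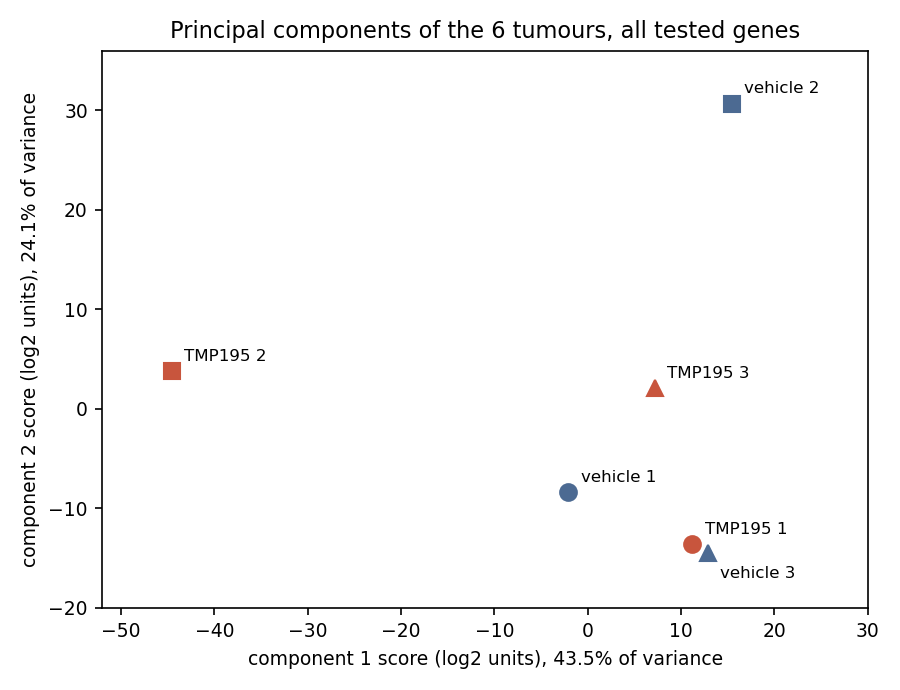
Scores of the 6 tumours on the first and second principal components of log2 intensity over all tested genes, in log2 units, with colour for the dosing group and marker shape for the replicate number. TMP195 tumour 2 lies alone at -44.6 on the first component, and vehicle tumour 2 lies highest on the second at 30.7.

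The first question was whether dosing with TMP195 altered transcript levels in the tumour as a whole, beginning with the enzymes it inhibits. Hdac4 averaged 7.91 ± 0.19 (SD, n = 3) in vehicle tumours and 7.98 ± 0.015 (SD, n = 3) in TMP195 tumours on the log2 scale, a difference of 0.07 with a 95% interval of -0.20 to 0.34. The differences were -0.06 for Hdac5 (interval -0.31 to 0.19), 0.03 for Hdac7 (-0.28 to 0.35) and 0.10 for Hdac9 (-0.26 to 0.47). Single tumours turned each sign: Hdac4 was -0.036 and Hdac7 -0.055 without vehicle tumour 2, Hdac7 -0.047 without TMP195 tumour 1, Hdac9 -0.035 without vehicle tumour 3 and Hdac5 0.014 without TMP195 tumour 3. Array weights turned Hdac7 to -0.065. Mef2a and Mef2d encode transcription factors that class IIa deacetylases bind and repress. Mef2a differed by 0.25 ± 0.14 (SE) and Mef2d by 0.19 ± 0.18 (SE). Of the 7 measured genes on the list of class IIa deacetylases and MEF2 factors, 6 were higher under TMP195 and 1 was lower, and limma's camera did not call the list (adjusted p = 0.31). With vehicle tumour 2 and TMP195 tumour 2 both left out, a choice made after seeing the data, the list median turned from 0.10 to -0.066 and Mef2d to -0.073, and Mef2a was 0.029. Without vehicle tumour 2 alone Mef2a was 0.12 and Mef2d 0.051, and without TMP195 tumour 2 alone they were 0.16 and 0.063. The list median was 0.051 without vehicle tumour 2, 0.063 without TMP195 tumour 2, 0.066 without TMP195 tumour 1 and 0.20 without TMP195 tumour 3.

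Macrophage marker transcripts were the next to be compared. Adgre1, which encodes the F4/80 antigen, averaged 6.94 ± 0.017 (SD, n = 3) under vehicle and 6.94 ± 0.19 (SD, n = 3) under TMP195, a difference of -1.54e-04 with a 95% interval of -0.27 to 0.27. Its sign turned with median centring (0.015), with cyclic loess (0.0036) and without vehicle tumour 1 (0.0096), TMP195 tumour 1 (0.029) or TMP195 tumour 3 (0.075). Csf1r, the receptor of the macrophage growth factor CSF1, differed by -0.04 (interval -0.39 to 0.30), and its sign turned without vehicle tumour 3 (0.051) and without TMP195 tumour 3 (0.075). Cd68, a lysosomal glycoprotein of macrophages, differed by -0.15 (interval -0.47 to 0.17), and by -0.029 without TMP195 tumour 3 and -0.28 without TMP195 tumour 2.

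**Figure D2:**
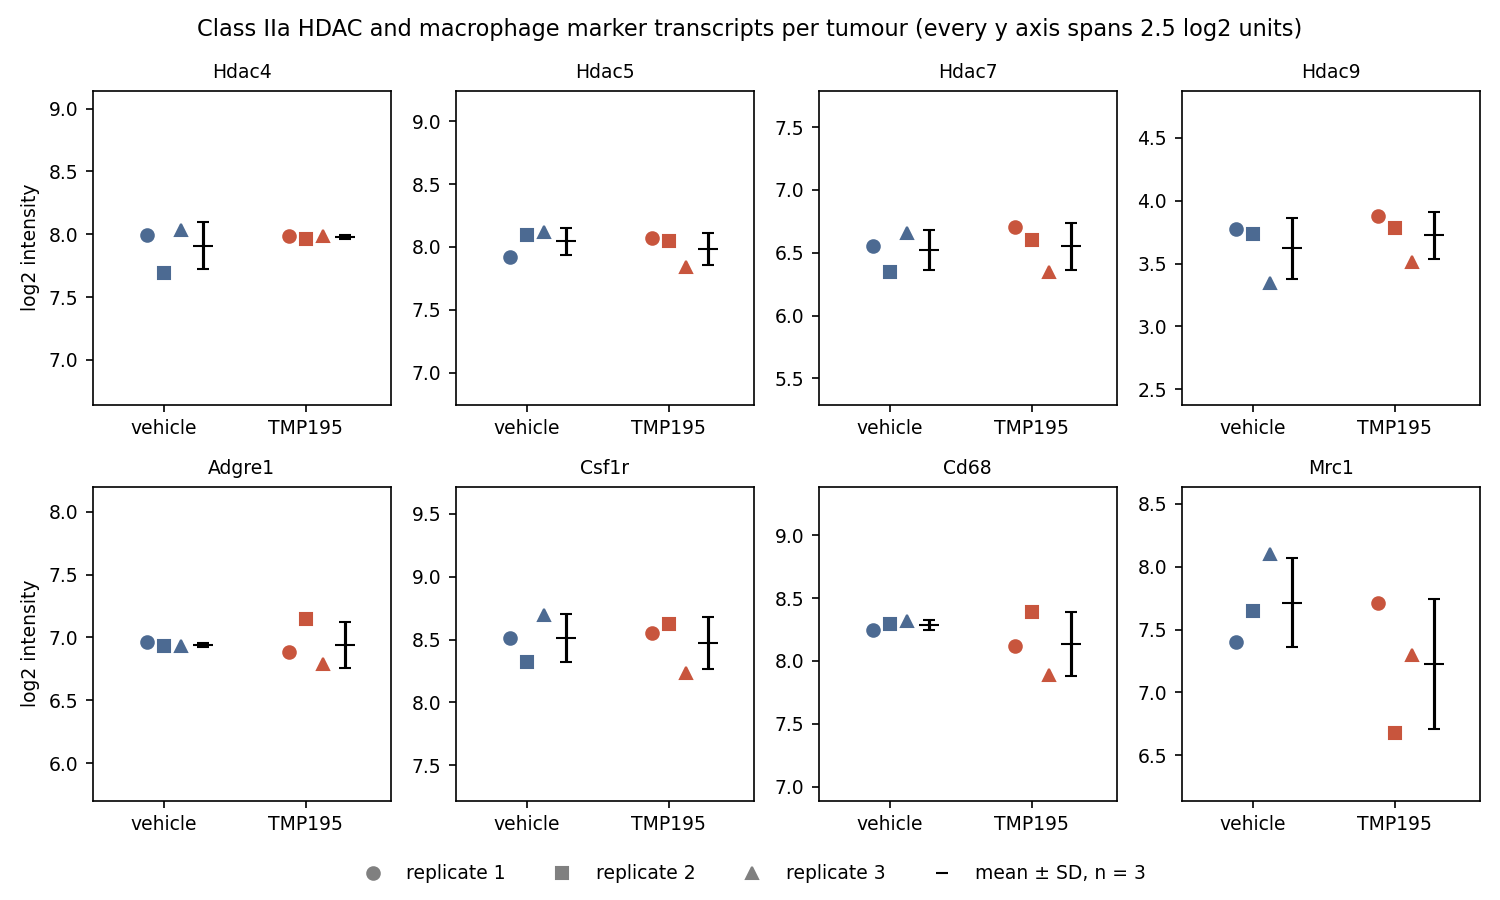
Log2 intensity of the transcripts of Hdac4, Hdac5, Hdac7, Hdac9, Adgre1, Csf1r, Cd68 and Mrc1 in each tumour, with the group mean and SD (n = 3) as a black bar beside the points. The groups overlap in every panel, and the difference of Hdac4 between group means is 0.07.

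Genes were named by the smallest unadjusted p among those that differed at least 1.5-fold without overlap of the groups. Higher in every TMP195 tumour than in any vehicle tumour were Hey1, a transcriptional repressor induced by Notch signalling (0.74 ± 0.19, log2 difference ± SE), Chn2, which encodes the Rac-inactivating protein beta-chimaerin (0.62 ± 0.18), Il1b, the cytokine interleukin-1 beta (0.80 ± 0.27), and Rtn1, a protein of the endoplasmic reticulum (1.12 ± 0.40). Luzp2, Vwc2, Afap1l1, Snord57 and the scaffold gene Akap12 lay between 0.63 and 0.83 higher. TMP195 tumour 2 carried much of these differences: without it Rtn1 differed by 0.63, Vwc2 by 0.47, Akap12 by 0.36, Snord57 by 0.32 and Afap1l1 by 0.30. Lower in every TMP195 tumour were Pcbd1, an enzyme of tetrahydrobiopterin recycling (-0.73 ± 0.13), Prtn3, a serine protease of myeloid granules (-0.90 ± 0.16), Pm20d1, a secreted enzyme that makes N-acyl amino acids (-0.85 ± 0.16), and the homeobox gene Hoxa5 (-1.26 ± 0.34). The ion channel gene Trpv3 and Chrdl2, an inhibitor of bone morphogenetic proteins, differed by -0.77 ± 0.17 and -0.60 ± 0.18. Pramel17 (0.68) and, on the lower side, Bcas1 (-0.59), Tas2r104 (-0.64), Ifna13 (-0.60) and Ppp4r3c-ps (-0.67) completed the 10 named in each direction, but their mean intensities ranked in the lowest 10% of genes. None of these 20 genes passed the test over all genes.

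No gene passed the threshold of an adjusted p of 0.05 among the 19937 tested with limma, and the smallest adjusted p was 1.00. At an unadjusted p under 0.05, limma gave 502 genes, of which 235 were higher and 267 lower under TMP195, where 997 would be expected by chance. The groups did not overlap in 1332 genes, or 6.68%, where chance gives 10%. A difference of at least 1.5-fold was seen in 254 genes, of which 100 were higher and 154 lower. The 90th percentile of the intervals' half-width was 0.53 on the log2 scale. What the test could find was gauged on simulated data with the same spread for each gene. The simulated genes varied independently of each other, so recovery in the real arrays may differ. Of 250 genes changed 2-fold, 72.4% were recovered, as were 93.2% of those changed 4-fold and 27.2% of those changed 1.5-fold, in simulations of 19937 genes with 200 changed genes each. Genes changed 1.5, 2, 4 and 8-fold were mixed in equal numbers and adjusted together. The strongly changed genes ease the threshold for the others. With fewer of them, recovery at 2-fold may be well below 72.4%.

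Gene groups were compared next, through 39 lists of cell type markers and process genes. With camera's preset correlation between genes, 5 lists passed an adjusted p of 0.05, 4 lower and 1 higher under TMP195. With a correlation estimated for each list, no list passed in camera, and the smallest adjusted p was 0.96. Among the 5 lists the estimates were 0.97 for skeletal muscle, 0.88 for adipocyte and 0.80 for proliferation genes. They were 0.32 for macrophage and 0.26 for circadian clock genes, where the preset was 0.01. Every camera call given below with tumours left out used the preset correlation and was not repeated with an estimated one or fry. No list passed with fry, limma's test of whether a list's genes move one way (smallest adjusted p 0.997). In the exact permutation test of list means, two-sided, 3 tumours against 3 cannot go below p = 0.10, and 0 lists reached that value where 3.9 would be expected. No member of any list passed over all genes. Adjusted over the list alone, 2 genes passed in limma: Cd209a, a lectin of dendritic cells (-0.52 ± 0.11 SE, adjusted p = 0.0335), and Chil3, a secreted chitinase-like protein of alternatively activated macrophages (0.48 ± 0.10 SE, adjusted p = 0.0300). That adjustment does not count that 39 lists were searched, so a few genes can pass it by chance. Every TMP195 tumour lay beyond every vehicle tumour in Cd209a and in Chil3, and Chil3 was dim, at percentile 9.07 of mean intensity. The list of alternative macrophage activation that holds Chil3 went the other way, with 9 of 14 members lower (median -0.072, camera adjusted p = 0.858). Its median turned without vehicle tumour 3 (0.039) or TMP195 tumour 2 (0.0083), and it was -0.19 without vehicle tumour 1. The dendritic cell list that holds Cd209a was lower in 8 of 14 (camera adjusted p = 0.523).

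Genes of the cell division cycle formed the list with the smallest p. Of 21 measured members, 20 were lower under TMP195, with a median of -0.22. The replication helicase genes Mcm5 and Mcm2 differed by -0.41 ± 0.25 (SE) and -0.32 ± 0.23 (SE), Rrm2, a subunit of ribonucleotide reductase, by -0.37 ± 0.27 and the mitotic activator Cdc20 by -0.32 ± 0.23. Without TMP195 tumour 2 these were -0.16 for Mcm5, -0.14 for Mcm2, -0.11 for Rrm2 and -0.096 for Cdc20, and without vehicle tumour 2 they were -0.23, -0.12, -0.19 and -0.15. Without TMP195 tumour 3 Mcm2 was -0.49 and Rrm2 -0.59. Camera gave the list an adjusted p of 5.22e-04 with the preset correlation, and an adjusted p = 0.96 with an estimated correlation. Mean log2 intensity of the list was 8.16, 8.57 and 8.10 in vehicle tumours 1 to 3 and 8.09, 7.68 and 8.38 in TMP195 tumours 1 to 3. Without vehicle tumour 2 the median was -0.076 (camera adjusted p = 0.185) and without TMP195 tumour 2 it was -0.036 (camera adjusted p = 0.773). Without TMP195 tumour 3 it was -0.39. With vehicle tumour 2 and TMP195 tumour 2 both left out, camera called the list higher (median 0.11, adjusted p = 0.0075), and the 4 genes turned, to 0.016 for Mcm5, 0.057 for Mcm2, 0.069 for Rrm2 and 0.074 for Cdc20. Over all alternatives camera and fry gave this list adjusted p values from 6.65e-10 to 0.997.

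The adipocyte list was lower in all 13 members, with a median of -0.92. Lep, the fat hormone leptin, differed by -1.01 ± 0.40 (SE), the lipid droplet genes Cidea and Plin4 by -0.92 ± 0.39 and -0.68 ± 0.63, and Car3, an abundant carbonic anhydrase of fat, by -1.97 ± 1.22. Car3 was -0.64 and Plin4 -0.31 without TMP195 tumour 2, without vehicle tumour 3 Cidea was -0.54 and Plin4 -0.13, without TMP195 tumour 1 Car3 was -3.21 and Plin4 -1.27, and without vehicle tumour 2 Plin4 was -1.04. Camera gave the list an adjusted p of 0.0013 with the preset correlation and an adjusted p = 0.96 with an estimated correlation. The list mean was 7.06, 6.19 and 8.51 in the vehicle tumours and 7.85, 5.16 and 6.16 in the TMP195 tumours, so the groups overlapped. Without vehicle tumour 3 the median was -0.12 (camera adjusted p = 0.490), and without TMP195 tumour 2 it was -0.10 (camera adjusted p = 0.635). Leaving out vehicle tumour 2 or TMP195 tumour 1 gave a median of -1.51 and -1.52. Adjusted p values ran from 1.19e-09 to 0.997 over the alternatives in camera and fry.

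Skeletal muscle genes were lower in all 12 members, with a median of -1.02. Pvalb, a calcium-binding protein of fast fibres, differed by -1.10 ± 0.69 (SE), and the myosin light chain genes Myl1 and Mylpf by -1.39 ± 0.93 and -0.89 ± 0.74. Mb, which encodes myoglobin, differed by -0.32 ± 0.24. Camera gave an adjusted p of 0.0013 with the preset correlation and an adjusted p = 0.96 with an estimated correlation. A single tumour carried the difference: the list mean was 7.95 in vehicle tumour 2 and between 4.43 and 4.92 in the other 5 tumours. Without vehicle tumour 2 the median turned to 0.21 (camera adjusted p = 0.171), Mylpf turned to 0.072, and Pvalb was -0.20, Myl1 -0.18 and Mb -0.032. Without vehicle tumour 1 or vehicle tumour 3 the median was -1.55 and -1.54 and Mylpf was -1.40 and -1.34, and Mb was -0.51 without vehicle tumour 1. With vehicle tumour 2 and TMP195 tumour 2 both left out, camera called the list higher (median 0.19, adjusted p = 0.0191). The adjusted p ran from 2.24e-06 to 0.997 over the alternatives in camera and fry.

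Macrophage markers were lower in 17 of 20 members, with a median of -0.12. Mertk, a receptor for the uptake of dying cells, differed by -0.47 ± 0.17 (SE), the mannose receptor gene Mrc1 by -0.49 ± 0.29, the lipid receptor gene Trem2 by -0.18 ± 0.09 and the lysozyme gene Lyz2 by -0.22 ± 0.13. Mrc1 was -0.21 and Lyz2 -0.14 without TMP195 tumour 2, Mrc1 was -0.30 without vehicle tumour 3, and Lyz2 was -0.14 without vehicle tumour 1. Camera gave the list an adjusted p of 0.0037 with the preset correlation and an adjusted p = 0.96 with an estimated correlation. The list mean was 7.26, 7.18 and 7.41 in the vehicle tumours and 7.19 and 7.27 in TMP195 tumours 1 and 2, and it was lowest in TMP195 tumour 3. Without vehicle tumour 3 the median was -0.071 (camera adjusted p = 0.288), and without TMP195 tumour 3 it was -0.030 (camera adjusted p = 0.450). The adjusted p ran from 1.02e-09 to 0.997 over the alternatives in camera and fry, and the median was -0.23 with vehicle tumour 2 and TMP195 tumour 2 both left out.

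Circadian clock genes were the list that camera called higher, with 11 of 12 members higher and a median of 0.16. Per1 and Per2, repressors in the clock's feedback loop, differed by 0.41 ± 0.16 (SE) and 0.35 ± 0.18. Arntl, its activator BMAL1, differed by 0.38 ± 0.16, and Nr1d2, which represses Arntl, by 0.18 ± 0.13. Per2 was 0.17 and Nr1d2 0.067 without vehicle tumour 2, without vehicle tumour 1 Per1 was 0.26, and without TMP195 tumour 2 Arntl was 0.21. Camera gave an adjusted p of 0.0037 with the preset correlation and an adjusted p = 0.96 with an estimated correlation. The list mean was 7.47, 7.30 and 7.55 in the vehicle tumours and 7.67, 7.67 and 7.49 in the TMP195 tumours. The call ended without vehicle tumour 2 (median 0.060, camera adjusted p = 0.185), without TMP195 tumour 1 (median 0.12, camera adjusted p = 0.126) and with both vehicle tumour 2 and TMP195 tumour 2 left out (median 0.080, camera adjusted p = 0.383). Without vehicle tumour 3 or TMP195 tumour 3 the median was 0.25. The adjusted p ran from 3.81e-04 to 0.997 over the alternatives in camera and fry. Times of tumour collection are not given in the sources used here. With limma's array weights, the camera calls of the circadian clock (adjusted p = 0.233), skeletal muscle (adjusted p = 0.233) and cell division (adjusted p = 0.823) lists ended too.

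**Figure D3:**
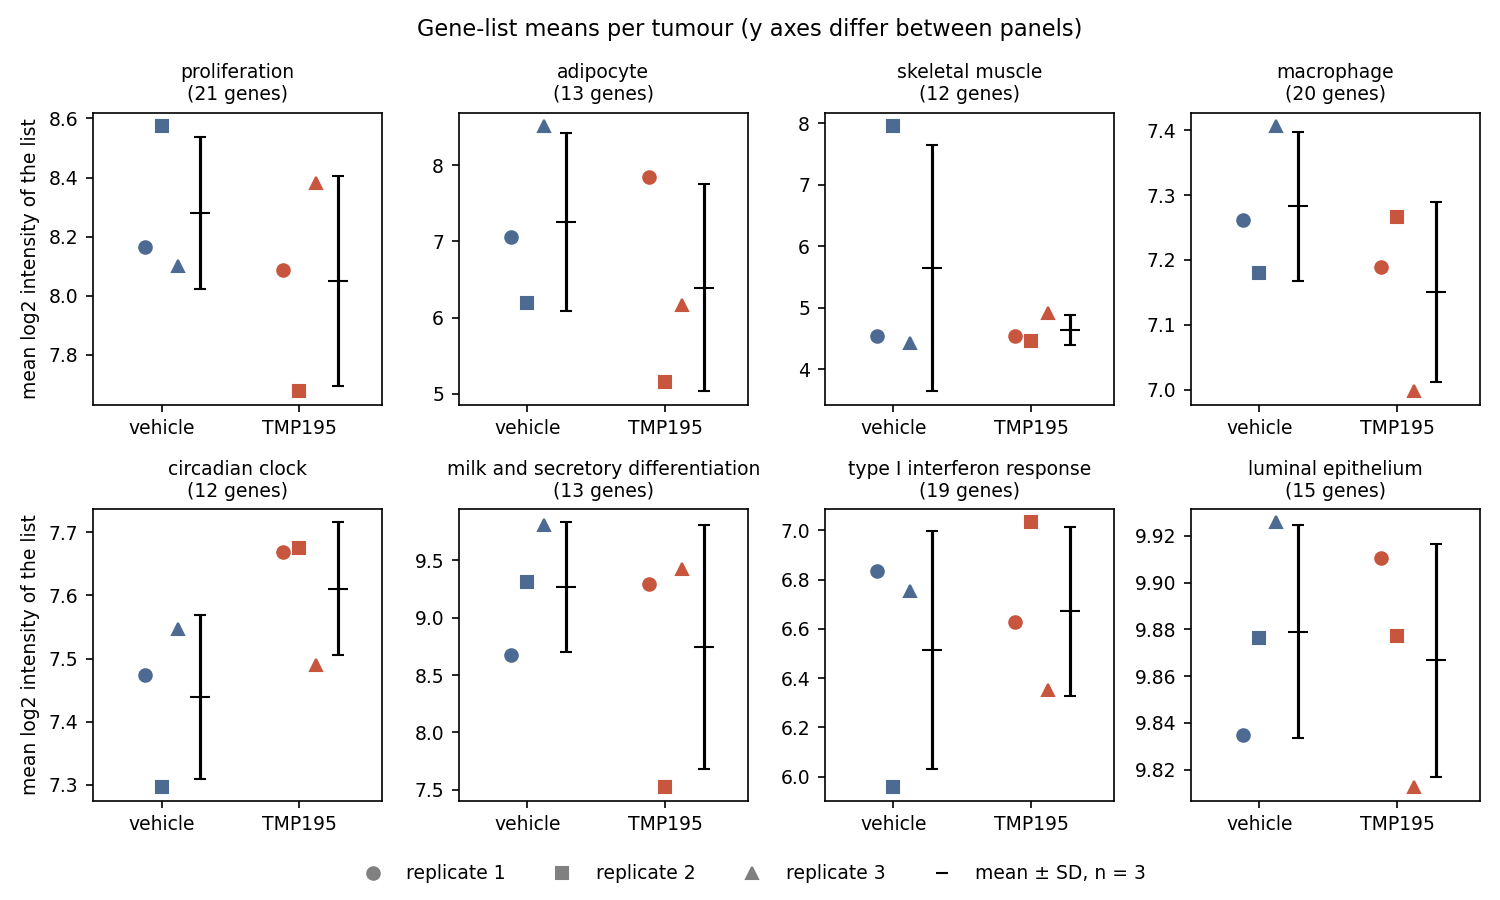
Mean log2 intensity of 8 gene lists in each tumour, with the group mean and SD (n = 3) as a black bar beside the points and a y axis of its own in each panel. In the skeletal muscle panel vehicle tumour 2 lies at 7.95 and the other 5 tumours lie between 4.43 and 4.92.

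Markers of other immune cells were not called by camera. In the T cell list 8 of 14 measured members were higher under TMP195 (adjusted p = 0.858), among them Cd28 at 0.28 ± 0.15 (SE) and Cd8b1 at 0.18 ± 0.10. In the cytotoxic and natural killer cell list 10 of 16 were higher (camera adjusted p = 0.584), with the receptor genes Klrd1 at 0.24 ± 0.11 and Ncr1 at 0.30 ± 0.15. The neutrophil list was split evenly at 7 and 7 (camera adjusted p = 0.548), with S100a8, a calcium-binding protein of neutrophils, at -0.80 ± 0.35 and the gelatinase gene Mmp9 at 0.54 ± 0.32. Inflammatory cytokines and chemokines were higher in 12 of 19 (camera adjusted p = 0.427), and Ccl8 differed by -0.81 ± 0.32. Phagocytic receptors and lysosomal genes were lower in 11 of 21 (camera adjusted p = 0.575), with the lysosomal protease gene Lgmn at -0.12 ± 0.08. Genes of MHC class II presentation were higher in 5 of 8 (camera adjusted p = 0.858). Among them were Cd74, the invariant chain, at 0.21 ± 0.22 and H2-Oa at -0.14 ± 0.15. Costimulation and checkpoint genes were higher in 9 of 12 (camera adjusted p = 0.310), including Tigit at 0.23 ± 0.11 and Cd274, which encodes PD-L1, at 0.19 ± 0.16. Mast cell genes were lower in 8 of 10 (camera adjusted p = 0.310), and camera called them lower without TMP195 tumour 1 (median -0.21, adjusted p = 0.0360, in a range from 0.0360 to 0.997), while the median went from -0.14 to -0.025 without TMP195 tumour 2. Without vehicle tumour 1 camera called the costimulation list higher (median 0.15, adjusted p = 0.0109), in a range from 0.0109 to 0.997 over the alternatives. Its median of 0.064 was 0.0028 without vehicle tumour 2, 0.023 without TMP195 tumour 2, 0.043 without vehicle tumour 3 and 0.12 without TMP195 tumour 1. Without vehicle tumour 2 camera called the phagocytic list lower (median -0.050, adjusted p = 0.0281), in a range from 0.0057 to 0.997. The phagocytic median of -0.013 turned without vehicle tumour 1 (0.014), vehicle tumour 3 (0.040) or TMP195 tumour 3 (0.0036). With vehicle tumour 2 and TMP195 tumour 2 both left out, camera called the MHC class II list lower (median -0.17, adjusted p = 0.0045, in a range from 0.0045 to 0.997), the phagocytic list lower (median -0.079, adjusted p = 0.0057), the dendritic cell list lower (median -0.079, adjusted p = 0.0333, in a range from 0.0333 to 0.997) and the neutrophil list lower (median -0.079, adjusted p = 0.0433, in a range from 0.0433 to 0.997). The MHC class II median also turned without vehicle tumour 2 (-0.024) or TMP195 tumour 2 (-0.095) alone. Without TMP195 tumour 2 the T cell median was -0.032, the cytotoxic and natural killer cell median -0.066 and the inflammatory median -0.0080, and Mmp9 was 0.14, Cd28 0.15, Cd8b1 0.12, Cd74 0.056, Cd274 0.065 and H2-Oa -0.25. Without TMP195 tumour 3 Klrd1 was 0.14, Ncr1 0.16, Cd28 0.44 and Cd274 0.32. Cd74 was 0.0063 and Cd274 0.096 without vehicle tumour 2, and Cd74 was 0.37 without vehicle tumour 3. The neutrophil median was 0.054 without TMP195 tumour 1 and 0.029 without vehicle tumour 1, and S100a8 differed by -0.36 without vehicle tumour 2. H2-Oa turned to 0.014 without TMP195 tumour 1, and Cd74 turned to -0.030 with array weights and to -0.15 with vehicle tumour 2 and TMP195 tumour 2 both left out, where Cd274 turned to -0.027 and the costimulation median to -0.034.

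Interferon and hypoxia genes were mostly higher, and camera called none of their lists. The type I interferon list was higher in 15 of 19 members (median 0.16, camera adjusted p = 0.183), with the RNA sensor gene Ddx58 at 0.29 ± 0.22 (SE) and the antiviral gene Mx2 at 0.37 ± 0.36. Its mean was lowest in vehicle tumour 2, at 5.96, and highest in TMP195 tumour 2, at 7.03. Its camera call depended on single tumours: it was called higher without vehicle tumour 1 (median 0.32, adjusted p = 0.0048), vehicle tumour 3 (0.24, adjusted p = 0.0043) or TMP195 tumour 3 (0.28, adjusted p = 0.0012). Without vehicle tumour 2 camera called it lower (median -0.090, adjusted p = 0.0367), Mx2 turned to -0.037, and Ddx58 was 0.078. Without TMP195 tumour 2 the median was 0.024, Ddx58 was 0.13 and Mx2 0.19. Ddx58 was 0.44 without vehicle tumour 1, and Mx2 was 0.56, 0.58 and 0.59 without vehicle tumour 1, vehicle tumour 3 or TMP195 tumour 3. With vehicle tumour 2 and TMP195 tumour 2 both left out camera called it lower as well (median -0.30, adjusted p = 1.04e-09), with Ddx58 at -0.073 and Mx2 at -0.21. That call took the preset correlation of 0.01, while the estimate for this list over all 6 tumours was 0.77. The list's adjusted p ran from 1.04e-09 to 0.997 over the alternatives in camera and fry. The interferon gamma list was higher in 10 of 13 (camera adjusted p = 0.264), with the chemokine gene Cxcl10 at 0.59 ± 0.28 and Ido1, an enzyme of tryptophan breakdown, at -0.40 ± 0.27. With vehicle tumour 2 and TMP195 tumour 2 both left out its median turned from 0.087 to -0.091, and it was 0.042 without vehicle tumour 2 alone and 0.044 without TMP195 tumour 2 alone. Ido1 was -0.12 without vehicle tumour 3 and -0.68 without vehicle tumour 1. The hypoxia and glycolysis list was higher in 13 of 17 (camera adjusted p = 0.183), with the oxygen sensor gene Egln3 at 0.70 ± 0.41 and the glucose transporter gene Slc2a1 at 0.13 ± 0.10. Camera called it without vehicle tumour 2 (median 0.19, adjusted p = 1.73e-04) and without TMP195 tumour 3 (median 0.19, adjusted p = 0.0418). The median went from 0.15 to 0.042 without vehicle tumour 1 and to 0.085 without vehicle tumour 3. Camera also called the list with the replicate number as a block (adjusted p = 0.0172) and with vehicle tumour 2 and TMP195 tumour 2 both left out (median 0.095, adjusted p = 0.0101). Without TMP195 tumour 2 alone the median was 0.028, Egln3 was 0.22, Slc2a1 0.063 and Cxcl10 0.28, and without TMP195 tumour 1 Egln3 was 1.10. The adjusted p of the hypoxia list ran from 1.73e-04 to 0.997 over the alternatives in camera and fry.

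Epithelial, stromal and vascular lists were not called by camera either. The luminal epithelium list was higher in 9 of 15 members (adjusted p = 0.936), and its mean was 9.88 ± 0.05 (SD, n = 3) under vehicle and 9.87 ± 0.05 (SD, n = 3) under TMP195. Within it the tight junction gene Cldn4 differed by -0.48 ± 0.19 (SE) and Elf5, a transcription factor of alveolar cells, by -0.19 ± 0.14, or by -0.054 without TMP195 tumour 2. Basal and myoepithelial genes were lower in 8 of 11 (camera adjusted p = 0.427). Camera called them lower without vehicle tumour 2 (median -0.25, adjusted p = 0.0281) and with vehicle tumour 2 and TMP195 tumour 2 both left out (median -0.20, adjusted p = 0.0199), in a range from 0.0199 to 0.997 over the alternatives, and their median was 0.0089 without vehicle tumour 3, -0.040 without TMP195 tumour 2, -0.15 without vehicle tumour 1 and -0.20 without TMP195 tumour 1. Milk and secretory genes were lower in 9 of 13 (camera adjusted p = 0.310), with the whey protein gene Wap at -1.60 ± 0.88 and Muc15 at 0.41 ± 0.26. Without TMP195 tumour 2 the median of the list turned from -0.35 to 0.077 (-0.19 without vehicle tumour 3, -0.68 without vehicle tumour 1, -0.55 without TMP195 tumour 3) and Wap differed by -0.54, and without vehicle tumour 2 Muc15 differed by 0.10, and Muc15 turned to -0.028 with both of these tumours left out. The mean of that list was 7.52 in TMP195 tumour 2 and between 8.68 and 9.81 in the other tumours. Fibroblast and collagen genes were lower in 12 of 17 (camera adjusted p = 0.384), with Fap at -0.37 ± 0.26 and the matrix protein gene Dpt at -0.73 ± 0.55. Endothelial genes were split at 9 and 9 (camera adjusted p = 0.584), with Sox17 at -0.36 ± 0.14 and the VEGF receptor gene Kdr at 0.19 ± 0.11. The p53 target list was higher in 9 of 13 (camera adjusted p = 0.575), with Zmat3 at 0.23 ± 0.20. Camera called the fibroblast list lower without vehicle tumour 2 (median -0.26, adjusted p = 1.52e-04) and without TMP195 tumour 1 (median -0.25, adjusted p = 0.0112). It was also called lower with array weights (median -0.19, adjusted p = 0.0143) and with vehicle tumour 2 and TMP195 tumour 2 both left out (median -0.13, adjusted p = 0.0106), in a range from 1.52e-04 to 0.997 over the alternatives. Its median turned without vehicle tumour 3 (0.057) or TMP195 tumour 2 (0.053), where Fap was -0.18 and -0.12 and Dpt -0.32 and -0.29. Fap was -0.56 without vehicle tumour 2, and Dpt was -1.28 without TMP195 tumour 1. Camera called the endothelial list higher without vehicle tumour 3 (median 0.089, adjusted p = 0.0400), in a range from 0.0400 to 0.997, and its median turned to -0.044 without vehicle tumour 2 and to -0.0094 without TMP195 tumour 1. Sox17 was -0.21 without TMP195 tumour 3. The p53 target median of 0.071 turned to -0.010 without vehicle tumour 1 and to -0.11 without TMP195 tumour 2, where Zmat3 was 0.027, and Zmat3 was 0.12 without vehicle tumour 1. Leaving out single tumours gave the p53 target list medians from -0.11 to 0.15. Median, mean and camera direction differed in sign in 5 of the 39 lists: luminal epithelium, pericyte, cholesterol synthesis, unfolded protein stress and TGF-beta signalling.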

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

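Leaving out vehicle tumour 2 and TMP195 tumour 2 together was chosen after seeing the data. Limma gave 0 genes past an adjusted p of 0.05 under every alternative with that threshold, and unadjusted counts from 243 to 938 beside 502. These counts rest on differing numbers of tests. The 243 came from the 13956 genes left without dim genes, and testing all 27359 probe sets gave 683. The 938, with array weights, and the 502 came from 19937 genes. A threshold of an unadjusted p under 0.05 with a fold of at least 1.5 gave 52 genes (16 higher, 36 lower), by its own looser construction. Leaving out single tumours gave 0 to 0 genes past the adjusted threshold.

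The 5 lists called by camera became 0 with an estimated correlation and 0 with fry, both of which take account of members that vary together, and 3 with array weights, which added the fibroblast list. Leaving out single tumours gave 4 to 8 lists, the most without vehicle tumour 2, and leaving out vehicle tumour 2 and TMP195 tumour 2 gave 15 (4 higher, 11 lower). Among these 15 were cholesterol synthesis, TGF-beta signalling, and epithelial-mesenchymal transition with matrix proteases. Camera also called cholesterol synthesis without vehicle tumour 2 alone and TGF-beta signalling without TMP195 tumour 2 alone. Every count with tumours left out rests on camera's preset correlation, and none was repeated with an estimated one or fry. Cyclic loess, median centring and leaving out dim genes each gave 5. The replicate number as a block gave 6, adding hypoxia and glycolysis. No tumour's deviations from its group mean correlated best with the tumour of the same number (-0.21, -0.063 and -0.097). With so few tumours, this gives no sign of pairing by number but cannot exclude it.

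Of 996 comparisons of 78 named genes with an alternative, 966 kept their direction and 30 turned, and no named gene passed the threshold in any (smallest limma adjusted p 0.649). Many of these comparisons could not turn. The replicate block, the trended robust prior and leaving out dim genes do not change a gene's difference. Genes named for groups that did not overlap keep their direction when a single tumour is left out. The 966 is therefore no measure of stability. Adgre1 was 0.015 with median centring and 0.0036 with cyclic loess. With array weights Hdac7 was -0.065 and Cd74 -0.030. Without both vehicle tumour 2 and TMP195 tumour 2, 13 genes turned: Hdac4 -0.027, Hdac7 -0.080, Mef2d -0.073, Mcm5 0.016, Rrm2 0.069, Cdc20 0.074, Mcm2 0.057, Mb 0.041, Muc15 -0.028, Cd74 -0.15, Ddx58 -0.073, Mx2 -0.21 and Cd274 -0.027. Leaving out single tumours gave ranges of -0.10 to 0.075 for Adgre1, -0.036 to 0.14 for Hdac4, -0.12 to 0.014 for Hdac5, -0.055 to 0.13 for Hdac7, -0.035 to 0.21 for Hdac9, -0.14 to 0.075 for Csf1r, -1.40 to 0.072 for Mylpf, -0.037 to 0.59 for Mx2 and -0.25 to 0.014 for H2-Oa. Beyond the tumours left out, the cause was not tested. Signal over background limits the genes named as dim.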

Other observations

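The tests of skeletal muscle and fat, of milk transcripts and of chromosome 11 were chosen only after the result was seen. Each of the 10 ways to split the 6 tumours into 3 and 3 was tested, which is too few for a share under 0.05. Limma gave 0 genes past an adjusted p of 0.05 in the real split and at most 0 in the others, and since every split was bound to reach a count of 0, 10 of 10 did and this says nothing on chance. At an unadjusted p under 0.05 the real split gave 502 genes and 9 of 10 splits gave as many, with 1371 as the highest of the others. Camera called 5 lists in the real split and at least as many in 10 of 10, with 21 as the highest of the others, for vehicle tumours 1 and 2 with TMP195 tumour 3 against the rest. All these list counts took camera's preset correlation, which lay below the estimated one for each of the 5 lists called in the real split. With an estimated correlation no list passed in the real split, and the other splits have no such count. Members of a list that vary together can therefore raise the counts in any split. The counts alone do not show a structure of the samples beyond that. In 22 of 39 lists the list mean varied within the groups more than in random lists matched on intensity, as members that vary together between tumours would give. The random lists were not matched on the spread of single genes. Lists of genes that each vary widely could therefore give this as well. For skeletal muscle, adipocyte, proliferation and type I interferon genes, estimated correlations of 0.97, 0.88, 0.80 and 0.77 between members argue against that. It stays open for lists with low estimates, such as fatty acid synthesis at 0.083.

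Skeletal muscle and fat genes differed between single tumours more than between the dosing groups. In vehicle tumour 2, Acta1 lay at 10.50, Ckm at 9.01 and Atp2a1 at 8.85 on the log2 scale, while no other tumour exceeded 6.67, 5.90 and 4.93. Without that tumour the median difference of the muscle list was 0.21, which argues against a lower level of muscle genes under TMP195 in general and is consistent with skeletal muscle tissue in vehicle tumour 2. Of the 12 muscle genes, 0 are on another list and 6 lay above the 30th percentile of intensity in every tumour. In the remaining muscle genes, low signal could hide a decrease. Whether the muscle came from the dissection was not tested.

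For the adipocyte list, 2 of the 3 vehicle tumours lay below the highest TMP195 tumour. Fabp4 was 9.62 in vehicle tumour 3, 8.97 in TMP195 tumour 1 and 4.64 in TMP195 tumour 2. Differing amounts of fat between tumours of either group may account for the list's difference. Of its 13 genes, 0 are on another list and 11 lay above the 30th percentile in every tumour. An effect of TMP195 on fat in some tumours stays open.

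TMP195 tumour 2 lay apart from the other 5. Against their median, Csn2 differed by -5.19, Wap by -3.28 and Car3 by -4.39 in this tumour, and Klk10 by 3.82, Mmp13 by 3.08, Hey2 by 2.84 and Lef1 by 2.21. The median difference of the luminal epithelium list was -0.055, and lists of other cell types moved apart, with fibroblast at -0.48 and adipocyte at -1.82 but T cell at 0.15 and cytotoxic and natural killer cell at 0.12, which argues against more non-epithelial tissue of all kinds alike. A further 84 genes outside the milk list lay more than 2-fold below every other tumour, which argues against a loss of the milk list's transcripts alone. The 84 include the fat genes Car3 and Fabp4 and the secretory gene Pip, so the count does not show how wide the loss was. A modest share of added immune cells, which the high level of the luminal genes would hide, a tumour of another differentiation state and a stronger response to TMP195 in a single mouse stay open, as untested.

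Part of what set TMP195 tumour 2 apart lay in runs of neighbouring genes on chromosome 11. These held 25 of the 150 genes that lay more than 2-fold above every other tumour in TMP195 tumour 2. Across all chromosomes, 57 windows of 9 neighbouring genes had in this tumour a median difference above 0.5 on the log2 scale, against at most 14 in 1000 shuffled gene orders, and 3 runs on that chromosome held 53 genes: Pitpnc1 to Prkar1a (median 0.95), Fads6 to Tsen54 (1.07) and Tnrc6c to C1qtnf1 (1.26). Other windows passed the shuffled orders too: in this tumour the lowest lay at -2.53 around Csn1s2a in the casein cluster of chromosome 5 (lowest shuffled -1.26), and vehicle tumour 3 had 5 windows above 0.5 (at most 1 shuffled), the highest at 0.60 around Cd209a on chromosome 8 (highest shuffled 0.51), so a gene family that varies together can pass this test as well. The genes of the chromosome 11 runs had medians of -0.13 and 0.064 in TMP195 tumours 1 and 3, which argues against a response shared by the TMP195 tumours. Extra copies of these segments in that tumour are a candidate explanation, but copy number was not measured, and a response in that tumour alone stays open.

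Values of the other tumours belong to no comparison. In vehicle tumour 2 the type I interferon list lay at -0.71 against the median of the others, with 17 of 19 members below, the proliferation list lay at 0.51, with 21 of 21 above, and Muc4 at 2.82. In vehicle tumour 3 the fat genes Pck1 and Ucp1 lay at 3.83 and 3.21. In TMP195 tumour 1 the salivary and secretory genes Pip and Bpifa2 lay at 2.76 and 1.54, and in TMP195 tumour 3 the demilune cell genes Dcpp2, Dcpp1 and Dcpp3 lay at 3.78, 2.29 and 1.54. In vehicle tumour 1 the small nucleolar RNAs Snord58b and Snord42a lay at -1.80 and -1.68.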
